A study of Mus musculus with 106 samples.

How the data were processed

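Promoter-capture Hi-C joins DNA fragments that lie close together in the nucleus, enriches the ligated pairs that contain a promoter with a probe set, and counts the read pairs of each joined pair by sequencing. The labels describe mouse gonadal fat pad (called adipose here), pancreatic islet and liver, digested with DpnII, filled in with biotin, ligated in place and captured with a custom probe set. Mice of the strains C57BL/6J (B6), NZO/HlLtJ (NZO) and CAST/EiJ (CAST), of both sexes, ate a diet of 10% fat plus fiber (low-fat) or 44% fat plus fiber (high-fat). Each of the 36 combinations of tissue, strain, sex and diet holds 3 libraries, except female low-fat CAST adipose and male high-fat B6 islet with 2, which makes 106 libraries. The labels do not state that the libraries came from separate animals, so every p-value here measures the spread between these libraries.

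Per the labels the authors processed the reads on the build mm10, and the aligner and the interaction caller are not given in the sources used here. The deposited counts are the read pairs that join the 2 fragments of a called interaction, as whole numbers from 2 upward without normalization. The deposited score is the interaction caller's own value for each interaction, and the lowest in any library is 5. The authors listed called interactions alone, so a pair that is absent has no value. The files carry no gene names and no strand.

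The deposited intervals, called fragments here, numbered 360090 in any called interaction, with a median length of 5291 bp, and 47445 of them were baited. Whether each is a single DpnII fragment was not examined. Since no strand is given, both ends of each protein-coding gene of the mm10 annotation were looked up among the baits, which placed 20537 of 21900 genes. A gene with 1 baited end, or with both ends in 1 bait, took that bait (12779 and 2431 genes). With ends on different baits, it took the end not shared with another gene where exactly 1 was unshared (2121 genes), and otherwise the sum of both (2627 genes). With no baited end it took the baits inside the gene (579 genes). Genes with identical baits formed 1 unit. These units are called promoters here, although without a strand some values may be those of the other end of the gene or of a bait inside it. With 1395 long non-coding genes on baits that held no coding gene, this gave 21115 promoter units.

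The main measure was the number of called cis interactions (both fragments on 1 chromosome) of each promoter in each library. Libraries held 40 to 189559 called cis interactions, with a median of 42983.5. The medians were 59463 in adipose, 24115 in islet and 41810.5 in liver. In these cis interactions, libraries held 455 to 1.63395e+06 read pairs. Of the 106 libraries, 8 islet libraries had under 1000 called cis interactions and were left out by the minimum of 2000. They were the 3 male low-fat NZO libraries, female low-fat NZO replicate 3, female high-fat NZO replicates 2 and 3, and female high-fat CAST replicates 1 and 2. The 98 libraries used were 35 adipose, 27 islet and 36 liver. Replicate numbers follow the order of the deposition and pair nothing across tissues.

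Counts per promoter were tested with the edgeR 4.0.16 quasi-likelihood test after trimmed-mean normalization, with promoters kept by filterByExpr at a count minimum of 3. Strain, sex, diet and tissue were terms of each fit where they were not the contrast, together with the log10 of the library total. Each tissue was set against the mean of the other tissues over all libraries, and strain, diet and sex were tested within each tissue. Diet and sex were also tested over all tissues. The threshold was a Benjamini-Hochberg adjusted p of 0.05. Fold changes are given on the log2 scale with their standard error (SE), and levels as the mean number of called interactions per library ± the standard deviation (SD).

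Single interactions were tested as called or not called with limma 3.58.1, for the 112597 cis interactions called in at least 10 libraries. Library measures (number of calls, promoter-promoter share, median distance and X-chromosome share) were compared with two-sided permutation tests of 100000 resamples, and adjusted over 12 tests. The overlap of the 5000 highest-scored cis interactions between libraries was measured by the Jaccard index, with 10000 one-sided permutations of the tissue labels.

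The 13 gene lists held genes of islet endocrine cells, adipocytes, hepatocytes, exocrine pancreas, macrophages, endothelium, and stroma with mesothelium, mouse counterparts of genes near type 2 diabetes association signals, lipid metabolism, inflammation, liver genes of known sex bias, genes that escape X inactivation, and housekeeping genes. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. The genes named in each tissue comparison are the 8 highest and 4 lowest log2 changes past the threshold with a mean of at least 5 called interactions in the higher group. Up to 5 each way were taken in the other comparisons, and members of the lists were named too. Symbols made of Gm and digits, symbols that end in Rik, bare identifiers and baits with more than 1 symbol were passed over. Single interactions named are the 3 smallest p-values among the interactions called more often whose bait holds a gene of the tissue's list, and the 3 smallest p-values of any bait with a single symbol. The number of libraries that show a direction counts those on that side of the median of the other group, in called interactions per 10000 cis interactions. For a rise where most of the other libraries held no call, this is the number of libraries with any call.

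The designs, tests, gene lists, naming rule and other settings were chosen before the data were examined. The other settings were DESeq2 1.42.0, no filter, no depth covariate, a score of at least 7, other library minimums (all libraries, or 10000), the number series of the sample titles as a block, summed reads, between-chromosome calls included, and leaving out each replicate. For single interactions they also included Fisher's exact test, bins of 10 kb and calls in at least 5 libraries. Once the data were examined, the libraries were seen to fall into classes by the median distance of their calls, and a division at 90 kb was added. The fits were then repeated with this distance class as a block and within the long-distance libraries. Both, and the fits without the 5 libraries with over 50% between-chromosome calls, were chosen after seeing the data. Within islet the long-distance libraries hold no NZO and 1 CAST library among 7, so the strain contrasts could not be fitted there, and a smaller model for diet and sex was not run.

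The fits were tested on simulated data in which known promoters were changed by 1 log2 unit. Of the changed promoters tested, 68.9% were called in the islet comparison, with 8 false calls, of 10608 promoters tested of which 196 were changed. In the diet comparison over all tissues 85.1% were called, with 7 false calls, of 10740 tested and 194 changed. Within 1 tissue the diet comparison recovered 51.1% in liver, 36.3% in adipose and 9.8% in islet. Other tools were R 4.3.3 with version 1.17.8 of data.table, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.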

Results

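The data are promoter-capture Hi-C maps of mouse gonadal adipose tissue, pancreatic islet and liver, given as the called interactions of each library. B6 is a common laboratory strain, NZO a strain that becomes obese and diabetic, and CAST a wild-derived strain that is genetically far from both. The 98 libraries used were 35 B6, 33 CAST and 30 NZO. In adipose there were 12 B6, 12 NZO and 11 CAST libraries, in islet 11, 6 and 10, and in liver 12 of each. Called cis interactions per library ranged in these from 3637 to 189559 in adipose, from 2898 to 146809 in islet and from 14096 to 179708 in liver. Over all libraries, used or not, mean log10 numbers of calls were 0.75 higher in adipose than in islet (adjusted p = 0.00038) and 0.67 higher in liver than in islet, an islet minus liver difference of -0.67 (adjusted p = 0.00081). Adipose and liver differed by 0.08 (adjusted p = 0.24).

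The libraries fell into classes by the distance their interactions spanned. In 65 long-distance libraries the median distance was 99.3 to 125 kb and the mean was 11.5 to 20.7 read pairs per interaction. In 33 short-distance libraries the median was 49.0 to 80.6 kb with 5.05 to 8.48 read pairs. Short-distance libraries made up 20 of 27 in islet, 11 of 35 in adipose and 2 of 36 in liver. By strain they were 8 of 11 in CAST adipose, 3 of 12 in B6 adipose, 0 of 12 in NZO adipose, 9 of 10 in CAST islet, 5 of 11 in B6 islet and 6 of 6 in NZO islet. Both short-distance liver libraries were B6. The class therefore goes with islet and with strain in adipose and islet, and values with the class as a block stand beside the counts.

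**Figure D1:**
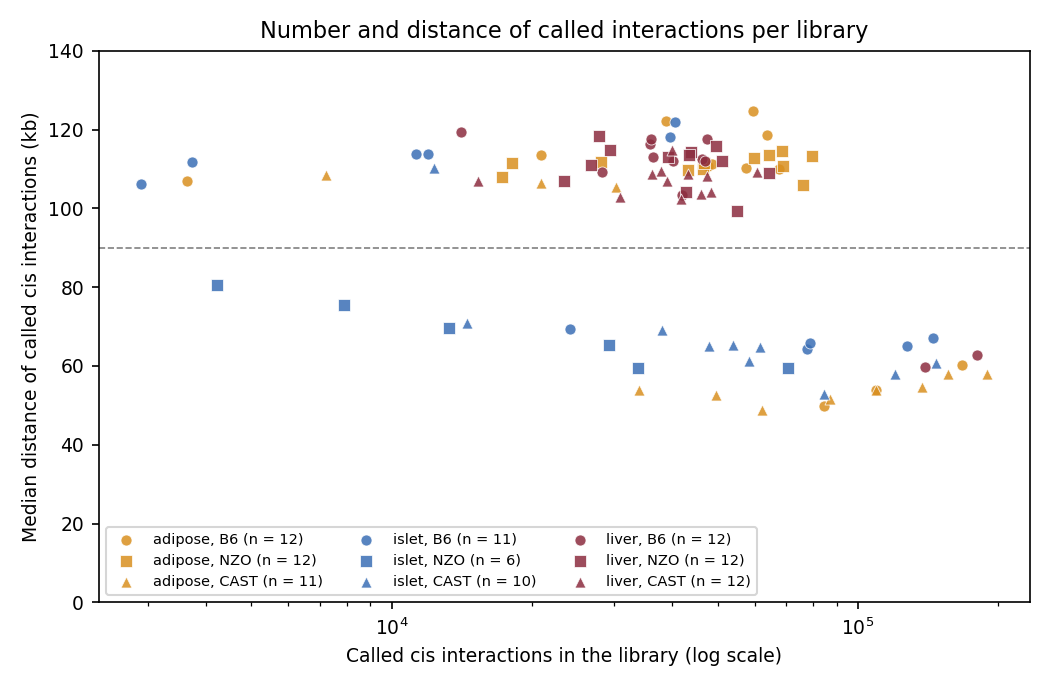
Number of called cis interactions per library (log axis) against the median distance of these interactions in kb, with tissue and strain marked and a dashed line at 90 kb. The 65 long-distance libraries lie at 99.3 kb or above and the 33 short-distance libraries at 80.6 kb or below.

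The tissue comparisons ask which promoters make more contacts in a tissue relevant to type 2 diabetes than in the others. In islet, Foxa2, a forkhead factor of endoderm-derived cells, had 3.22 ± 3.12 called interactions per islet library (SD, n = 27), against 0.571 ± 1.01 in adipose (n = 35) and 0.0833 ± 0.368 in liver (n = 36). Its log2 fold change was 3.28 ± 0.27 (SE, edgeR adjusted p = 4.79e-21), and 23 of 27 islet libraries lay above the median of the others. Neurod1, a transcription factor of endocrine cells, rose by 2.68 ± 0.31 (adjusted p = 5.31e-13; 19 of 27 libraries). Pcsk2, which cleaves prohormones, rose by 2.67 ± 0.28 (adjusted p = 2.23e-14; 21 of 27 libraries). Most of the 71 other libraries held no call (58 for Foxa2, 56 for Neurod1 and 57 for Pcsk2). These library counts are therefore of islet libraries with any call, and 4, 8 and 6 islet libraries held none.

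Of the 11 tested islet endocrine genes, 6 rose and 4 fell, and the counts adjusted over the list alone were also 6 and 4. The other genes that rose were the hormone gene Ppy (1.42 ± 0.22), Abcc8 (1.25 ± 0.26) and Kcnj11 (0.71 ± 0.19), which encode the ATP-sensitive potassium channel, and the transcription factor gene Pax6 (0.60 ± 0.19). Those that fell were Hhex (-1.24 ± 0.30), a transcription factor gene of liver and pancreas development, Ero1b (-1.07 ± 0.26), Mafa (-0.58 ± 0.25) and Ptprn (-0.57 ± 0.23). The insulin gene Ins2 was not called (-0.29 ± 0.20, adjusted p = 0.292). As a list they did not pass camera (adjusted p = 0.225). In a fit with distance class as a block, 6 rose and 1 fell, and the list passed (adjusted p = 7.82e-05, and 6.93e-04 with an estimated correlation).

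Among 26 tested genes near type 2 diabetes association signals, 9 rose and 5 fell in islet, with the same counts when adjusted over the list alone. Among those that rose besides Foxa2, C2cd4b rose by 2.09 ± 0.27, the unit shared by Hnf4a and R3hdml by 1.76, Wfs1 by 0.99 ± 0.30, C2cd4a by 0.77, Cry2 by 0.74, Kcnj11 by 0.71 and Cdc123 by 0.41. Zmiz1 (-1.85 ± 0.38), Camk1d (-1.26 ± 0.28), Hhex (-1.24), St6gal1 (-0.88) and Gckr (-0.68), which encodes the inhibitor of glucokinase, fell. The list did not pass camera (adjusted p = 0.225). With the class as a block, it did (adjusted p = 0.0394, and 0.0281 with an estimated correlation) with 6 higher and 2 lower, and Wfs1 was no longer called (0.22, adjusted p = 0.697).

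**Figure D2:**
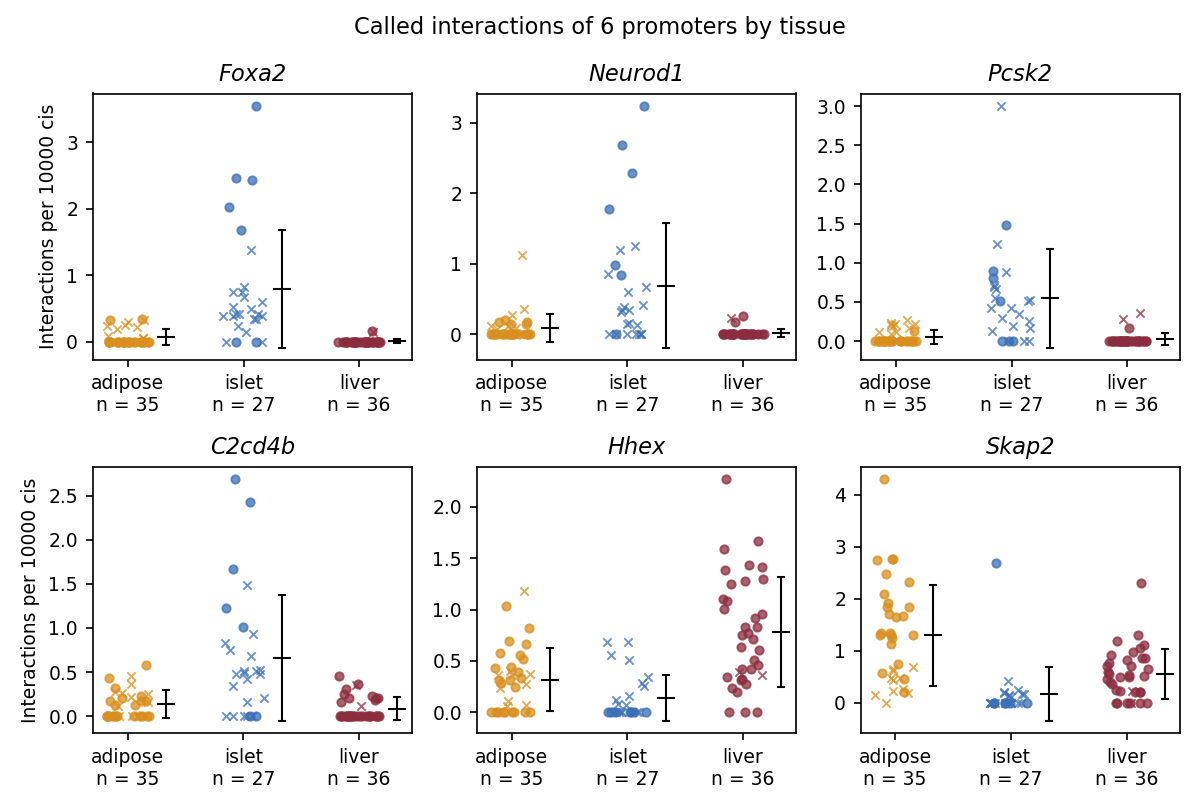
Called interactions per 10000 called cis interactions of each library for the promoters of Foxa2, Neurod1, Pcsk2, C2cd4b, Hhex and Skap2 in adipose (35 libraries), islet (27) and liver (36). Circles are long-distance and crosses short-distance libraries, and bars are the mean ± SD. Foxa2, Neurod1, Pcsk2 and C2cd4b are highest in islet, Hhex in liver and Skap2 in adipose.

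Genes of other cell types also moved in islet. Of 8 tested exocrine pancreas genes 6 rose, also when adjusted over the list alone, among them the digestive enzyme gene Cela3b (1.22 ± 0.28). This list had an adjusted p of 0.14, and with distance class as a block 2 rose (adjusted p = 0.26). Of 9 tested macrophage genes 5 fell and 0 rose by the edgeR test, and 5 fell and 1 rose when adjusted over the list alone. They included Ptprc, the pan-leukocyte CD45 gene (-2.08 ± 0.42), and Adgre1 (-1.24 ± 0.35). This list had an adjusted p of 0.183, and of 0.0118 with the class as a block. Of 13 tested hepatocyte genes 3 rose and 2 fell, also over the list alone (adjusted p = 0.508; 0.0221 with the class as a block, with 4 higher and 0 lower). The plasma protein gene Ahsg rose by 1.84 ± 0.25 and the urea cycle gene Ass1 by 1.52 ± 0.27. Of 24 adipocyte genes 5 rose and 4 fell, also over the list alone (adjusted p = 0.613). Of 5 stroma and mesothelium genes 3 rose, also over the list alone, among them the collagen gene Col1a1 (0.88 ± 0.18; list adjusted p = 0.102). Of 7 endothelial genes 1 fell, and 0 when adjusted over the list alone (adjusted p = 0.561). Of 10 housekeeping genes 8 fell, also over the list alone, among them Actb (-0.95 ± 0.14), and the list passed camera (adjusted p = 0.0143). That call was lost with an estimated correlation (adjusted p = 0.111) and with the class as a block (adjusted p = 0.0972).

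In the whole islet comparison 2877 promoters were higher and 2549 lower than in the mean of adipose and liver, of 10963 tested. The largest rises among promoters with at least 5 calls per islet library were Pcmtd2 (2.34 ± 0.21), Barhl1, a homeobox gene (2.11 ± 0.22), Shank2, a synaptic scaffold gene (2.06 ± 0.22), Sall4, a zinc finger gene (2.02 ± 0.22), Decr2 (1.88 ± 0.27), Efcab6 (1.87 ± 0.22), Klc2 (1.83 ± 0.27) and the circadian gene Ciart (1.76 ± 0.32). The baits of Pcmtd2, Shank2 and Efcab6 lie inside the gene and not at an end. The largest falls were the interferon-induced GTPase genes Tgtp1 (-2.36 ± 0.31) and Ifi47 (-2.32 ± 0.28), the prostaglandin receptor gene Ptger2 (-2.28 ± 0.30) and the immune adaptor gene Skap2 (-2.27 ± 0.33). In the fit blocked by distance class, the counts were 1039 and 623, with 1211 of the 5426 called promoters still called. Ciart then had -0.05 (adjusted p = 0.925) and Klc2 0.52 (adjusted p = 0.0943). Within the long-distance libraries 692 were higher and 652 lower, and without the depth covariate the counts were 1778 and 2398. The balance depended on the scaling, with 5358 higher and 2680 lower by summed reads, 5439 and 3218 without a filter, 2691 and 2955 by DESeq2 and 2560 and 2977 with all libraries.

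In adipose, the promoter of Skap2 had 5.94 ± 3.43 called interactions in adipose (SD, n = 35), 0.556 ± 0.892 in islet (n = 27) and 2.39 ± 2.10 in liver (n = 36), a log2 fold change of 2.02 ± 0.22 (edgeR adjusted p = 2.47e-12) that 32 of 35 libraries showed. Its bait lies on chromosome 6 from 52007984 to 52015356 (mm10). Cav1, the main caveolin gene of fat cells, had 5.71 ± 4.61 against 2.85 ± 2.54 in islet and 0.917 ± 1.05 in liver, a rise of 1.36 ± 0.22 (adjusted p = 1.85e-06; 28 of 35 libraries). Cd36, a fatty acid transporter gene, rose by 1.55 ± 0.30 and Lpl, the gene of lipoprotein lipase, by 0.82 ± 0.26. The other large rises were Cped1 (1.57 ± 0.16, bait inside the gene), Epb41l2 (1.56 ± 0.19), the kinase gene Nek9 (1.46 ± 0.21), Psen2 (1.40 ± 0.19), the histone gene H1f3 (1.37 ± 0.24) and Arrdc3 (1.37 ± 0.23). The largest falls were Lcn12 (-1.33 ± 0.20), Amt (-1.01 ± 0.28), Ppp1r16a (-1.01 ± 0.14) and Fbxw5 (-1.01 ± 0.23).

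Of 24 tested adipocyte genes 6 rose and 4 fell in adipose, also when adjusted over the list alone (camera adjusted p = 0.606). Among those that rose besides Cd36 and Lpl were Mest (0.81 ± 0.23), Cebpb (0.72 ± 0.15) and Cebpa (0.60 ± 0.22). None of the 6 that rose was called within the long-distance libraries, where the changes were 1.79 for Cd36 (adjusted p = 0.0576), 0.73 for Lpl (0.304), 0.89 for Mest (0.111), 0.18 for Cebpb (0.567) and 0.50 for Cebpa (0.45). Thrsp (-0.68 ± 0.24), the adrenergic receptor gene Adrb3 (-0.67 ± 0.19), the fatty acid synthase gene Fasn (-0.64 ± 0.17) and Cfd (-0.47 ± 0.18) fell. Of 7 endothelial genes Flt1 (0.92 ± 0.28), Sox17 (0.77 ± 0.24) and Pecam1 (0.68 ± 0.21) rose, also over the list alone (adjusted p = 0.139). Of 9 macrophage genes 3 rose (Ptprc 0.81 ± 0.29, Cd14 0.63 ± 0.18, Fcer1g 0.29 ± 0.11) and 2 fell (Spi1 -0.80 ± 0.19, Tyrobp -0.74 ± 0.28), or 4 and 2 when adjusted over the list alone (adjusted p = 0.675). Of 26 genes near type 2 diabetes signals 2 rose, Zmiz1 (1.32) and Zfand6 (0.84), and 4 fell, or 3 and 6 adjusted over the list alone (adjusted p = 0.59). Of 10 housekeeping genes 5 rose and 0 fell by edgeR, also over the list alone (adjusted p = 0.0919). Islet endocrine genes (11 tested, adjusted p = 0.556), hepatocyte genes (13, adjusted p = 0.338) and exocrine genes (8, adjusted p = 0.59) each had 1 higher and 1 lower, also over the list alone. None of the 5 stroma genes was called (adjusted p = 0.59).

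Over all promoters 1290 were higher and 884 lower in adipose, of 10963. With distance class blocked, 809 were higher and 978 lower, with 1439 of the 2174 still called, and without the depth covariate 1231 and 368. Without 1 replicate of every group 997 to 1319 were called in all. Within the long-distance libraries 440 and 448 were called, where Arrdc3 (0.69, adjusted p = 0.101) and Ppp1r16a (-0.93, adjusted p = 0.0907) were not.

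In liver, the promoter of Ifi47 had 6.72 ± 2.95 called interactions in liver (SD, n = 36), 4.66 ± 3.73 in adipose (n = 35) and 0.815 ± 1.24 in islet (n = 27), a rise of 1.66 ± 0.20 (edgeR adjusted p = 2.79e-12; 35 of 36 libraries). Hhex rose by 1.40 ± 0.23 (adjusted p = 2.96e-07; 33 of 36 libraries) and Gckr by 0.67 ± 0.15 (32 of 36 libraries). The other large rises were Tlr9, which senses foreign DNA (1.64 ± 0.21), Tgtp1 (1.5 ± 0.22), Hes2 (1.43 ± 0.15), Dcps (1.41 ± 0.22), Fbxw5 (1.36 ± 0.20), Lcn12 (1.35 ± 0.17) and Coq2 (1.35 ± 0.21). The largest falls were Pcmtd2 (-2.24 ± 0.26), the actin regulator Enah (-2.02 ± 0.17; 3.22 ± 5.20 calls against 14 ± 11.7 in adipose and 13.8 ± 11.6 in islet), Cav1 (-2.0 ± 0.28) and Luzp1 (-1.96 ± 0.23). The Enah bait lies inside the gene.

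Of 13 tested hepatocyte genes 5 rose and 3 fell in liver, or 6 and 4 adjusted over the list alone (camera adjusted p = 0.827). Genes of plasma proteins were among those that rose, with Ttr (1.05 ± 0.23), Apoa1 (1.03 ± 0.20), Apoc3 (0.62 ± 0.22) and Apoa2 (0.24 ± 0.10). Ass1 (-1.43 ± 0.30), Ahsg (-1.20 ± 0.28) and the unit of Hnf4a and R3hdml (-1.15) fell. The list's median was 0.11 and its mean -0.06. In a fit with distance class as a block, none of the 5 that rose was called (Ttr 0.55, adjusted p = 0.101; Apoa1 0.29, adjusted p = 0.266), and 2 of the list fell. Of 9 macrophage genes 5 rose, also over the list alone (adjusted p = 0.167), among them Adgre1 (1.28 ± 0.27), Ptprc (1.27 ± 0.30) and Spi1, the gene of the myeloid factor PU.1 (0.96 ± 0.18). Of 26 genes near type 2 diabetes signals 5 rose (among them Hhex, Gckr, Camk1d 1.16 and St6gal1 0.53) and 9 fell, also over the list alone (adjusted p = 0.573), with Foxa2 at -2.82 ± 0.38 and C2cd4b at -1.51.

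Of the other lists in liver, the 11 islet endocrine genes had 3 higher (Hhex, Mafa 0.56 ± 0.21 and Ins2 0.43 ± 0.18) and 4 lower, or 5 and 5 adjusted over the list alone (adjusted p = 0.823). Ins2 was higher in 30 of 36 liver libraries (adjusted p = 0.0406), and with the class as a block it was not called (-0.03, adjusted p = 0.945). The 24 adipocyte genes had 5 and 8 (adjusted p = 0.573), the 8 exocrine genes 1 and 4 (adjusted p = 0.17), the 7 endothelial genes 2 and 2 (adjusted p = 0.621) and the 5 stroma genes 0 and 3 (adjusted p = 0.13), each also over the list alone. The 10 housekeeping genes had 6 higher and 0 lower by edgeR, or 7 over the list alone (adjusted p = 0.13). Over all promoters 2389 were higher and 2299 lower in liver, of 10963, a balance that turned to 2607 and 4197 with summed reads and 2767 and 3742 without a filter. With the class as a block, 1379 and 1278 were called, with 1855 of 4688 still called. Within the long-distance libraries 1433 and 879 were called, where Coq2 was not (0.62, adjusted p = 0.106).

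Single interactions could be placed at named loci. In islet, a contact of Ppy on chromosome 11 (bait 102098347 to 102103677) with the fragment from 102137492 to 102142754, 39.1 kb away, was called in 15 of 27 islet, 10 of 35 adipose and 2 of 36 liver libraries. The difference was 44.8 ± 8.21 percentage points (limma adjusted p = 1.66e-05; 0.00529 with distance class as a block). A contact of Neurod1 over 85.3 kb was called in 10 islet, 2 adipose and 1 liver libraries (adjusted p = 8.27e-04; 3.35e-06 with the block). A contact of Rfx6, a transcription factor gene of endocrine cells, over 96.1 kb was called in 9, 1 and 0 (adjusted p = 4.54e-05; 0.00137 with the block). The smallest p-values in islet were for contacts that were called less often there, of Tssc4 (5 of 27 islet libraries, all 35 adipose and all 36 liver libraries), Fxyd7 with Fam187b and Lsr (0, 30 and 31) and Plec with Cyc1 and Sharpin (4, 32 and 35).

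In adipose, a contact of Cebpa, the adipocyte differentiation factor, with the bait of Cebpg and Gm45095 63.4 kb away was called in 27 of 35 adipose, 3 of 27 islet and 23 of 36 liver libraries. The difference was 38.0 ± 8.81 points (adjusted p = 0.00443; 0.0478 with distance class as a block), and within the long-distance libraries 40.4 points (adjusted p = 0.093). A contact of Plin4, a lipid droplet gene, with Tnfaip8l1 (15, 4 and 1 libraries) differed by 29.7 points (adjusted p = 0.0134), and by 26.5 points with the block (adjusted p = 0.0501). The contacts of Rtn2 with Ercc1 (29, 1 and 8) and Rtbdn with Prdx2 (31, 6 and 10) had the smallest p-values with that of Tssc4. In liver, contacts of Apoa2 (33 liver, 26 adipose and 9 islet libraries) and Nr1i3 (32, 25 and 10) with Cfap126 differed by 36.7 and 34.0 points. Both were lost with the block (5.09 and 7.35 points, adjusted p = 0.83 and 0.758), and the Nr1i3 contact turned to -9.43 points within the long-distance libraries (adjusted p = 0.705). The contacts of Atp5d over 157.1 kb (36 liver, 15 adipose and 1 islet libraries), Wdr18 with Atp5d (34, 14 and 2) and Atp5d with Abca7 and Arhgap45 (34, 20 and 0) kept adjusted p-values of 2.10e-07, 3.18e-05 and 2.05e-05 with the block. Over 112597 interactions, 4308 were called more and 303 less often in adipose, 6535 and 16774 in islet, and 15141 and 6863 in liver. In the fit blocked by distance class, the counts were 1999 and 313, 564 and 507, and 1905 and 2945. The balance also moved with other settings, to 1745 and 22267 in islet by Fisher's exact test and 4020 and 4650 in liver with a score of at least 7. Without 1 replicate of every group 1073 to 2069 were called in adipose, 11499 to 13357 in islet and 10838 to 13027 in liver.

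The share of called cis interactions that joined a pair of baits was 56.6% ± 6.08 in liver (SD, n = 36), 49.9% ± 9.87 in adipose (n = 35) and 42.3% ± 9.13 in islet (n = 27). The permutation tests gave adjusted p = 0.0014 for adipose against liver, 0.0048 for adipose against islet and 4e-05 for islet against liver. The median distance was 107.6 ± 12.5 kb, 93.6 ± 27.5 kb and 78.0 ± 22.3 kb in the same order (adjusted p = 0.0084, 0.022 and 4e-05). Without replicate 3 of every group adipose against islet did not pass for the share or the distance (permutation adjusted p = 0.15 and 0.25). The distance of adipose against liver did not pass without replicate 2 (permutation adjusted p = 0.096) or at depths of 20000 to 60000 (0.15). In long-distance libraries alone the share was 57.9% ± 2.43 in liver (n = 34), 56.2% ± 3.56 in adipose (n = 24) and 56.4% ± 2.94 in islet (n = 7). There the exact test gave adjusted p = 0.85 for adipose against islet and 0.21 for islet against liver, and the permutation test 0.044 for adipose against liver. In short-distance libraries it was 36.1% in adipose (n = 11) and 37.4% in islet (n = 20; permutation adjusted p = 0.3).

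Pooled over the tissues, pairs of libraries of 1 tissue shared more of their 5000 highest-scored interactions than pairs of different tissues, with mean Jaccard indices of 0.0995 and 0.0624 (p = 0.0001, the smallest that 10000 permutations can give). This did not hold for each tissue: the mean was 0.145 within liver, 0.0963 within adipose and 0.0243 within islet, against 0.105 for adipose with liver, 0.0335 for adipose with islet and 0.0358 for islet with liver. Among pairs of 1 distance class the pooled means were 0.130 and 0.108 (permutation p = 0.0001, again the smallest). In long-distance libraries they were 0.160 and 0.126, and in short-distance libraries 0.0267 and 0.0309 (permutation p = 0.9). Libraries of 1 tissue and class shared more within a strain (0.141) than between strains (0.124; permutation p = 0.0001, the smallest).

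The strain comparisons set the diabetes-prone NZO and the wild-derived CAST against B6. Libraries of all strains were processed on the build mm10, and whether sequence that differs from this build gave some of the strain calls was not tested. In CAST liver, the sulfotransferase gene Sult3a1 had 5.83 ± 3.27 called interactions in CAST (SD, n = 12) and 0.833 ± 1.85 in B6 (n = 12), a log2 fold change of 4.68 ± 0.46 (edgeR adjusted p = 5.68e-12; 12 of 12 libraries), from a bait inside the gene. Hsd17b6, of steroid metabolism, rose by 2.50 ± 0.33, Cks1brt by 2.42 ± 0.38, Btbd9 by 2.38 ± 0.31 and Shank3 by 2.38 ± 0.24. Slfn8, of an immune-related gene family, had 0.667 ± 0.985 against 11.9 ± 4.81, a fall of -3.87 ± 0.34 (adjusted p = 1.43e-13; 12 of 12 libraries). The non-coding Unc45bos (-4.71 ± 0.42), Ssr2 (-4.21 ± 0.65), the trehalase gene Treh (-3.25 ± 0.45) and Ms4a6c (-2.91 ± 0.35) fell too.

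Of 17 tested genes near type 2 diabetes signals 2 rose and 2 fell in CAST liver, also over the list alone (camera adjusted p = 0.518). Gckr had 2.25 ± 1.29 called interactions in CAST and 7.83 ± 3.69 in B6, a change of -1.62 ± 0.27 (adjusted p = 9.72e-06; 12 of 12 libraries). Cobll1 had 0.25 ± 0.452 against 3.17 ± 2.44 (-3.05 ± 0.60). Kcnj11 had 4.58 ± 1.56 against 1.33 ± 1.16 (2.01 ± 0.36; 12 of 12 libraries), and the desaturase gene Fads1 rose by 1.26 ± 0.41. Fads1 was not called with distance class as a block (1.06, adjusted p = 0.11). Of 16 lipid metabolism genes 2 rose, Fads1 and the cholesterol synthesis gene Sqle (1.08 ± 0.37; 1.09 with the block, adjusted p = 0.0735), also over the list alone (adjusted p = 0.624). Of 16 adipocyte genes Cebpa (1.5 ± 0.41), Plin4 (1.54 ± 0.41) and Adrb3 (1.07 ± 0.34) rose and the glucose transporter gene Slc2a4 (-1.24 ± 0.37) fell, also over the list alone (adjusted p = 0.518). Of 8 hepatocyte genes Apoa2 (0.48 ± 0.13) and Ttr (1.33 ± 0.41) rose, also over the list alone (adjusted p = 0.383), and Ttr was lost with the block (0.76, adjusted p = 0.212). Of 7 islet endocrine genes 2 rose, or 3 over the list alone (adjusted p = 0.16). Of 7 macrophage genes 2 fell, or 3 with 2 higher over the list alone (adjusted p = 0.518). Over all promoters 600 were higher and 527 lower of 8463 tested. With distance class blocked, 1109 were called, and without the depth covariate 404 were higher and 543 lower. Without 1 replicate of every group 569 to 603 were called, and with summed reads 1704.

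In NZO liver, the heme synthesis gene Alad had 15.8 ± 4.62 called interactions (SD, n = 12) against 4.92 ± 4.21 in B6 (n = 12), a rise of 1.94 ± 0.22 (edgeR adjusted p = 2.39e-09; 12 of 12 libraries). Hdhd3, on the neighbouring bait, rose by 1.56 ± 0.36, with the olfactory receptor gene Olfr112 (2.90 ± 0.40), St6galnac2 (2.30 ± 0.36) and the vomeronasal receptor gene Vmn1r235 (1.83 ± 0.35). The class I histocompatibility gene H2-K1 had 1.42 ± 0.793 against 10.8 ± 10.2 (-2.52 ± 0.35; 12 of 12 libraries). Unc45bos (-3.33 ± 0.34), Slfn8 (-2.39 ± 0.27), Snx5 (-2.31 ± 0.44) and Slc9a3r2 (-2.19 ± 0.30) fell too. Over all promoters 93 were higher and 85 lower of 8463, and DESeq2 called 93 in all. Without 1 replicate of every group 78 to 90 were called, and with summed reads 675 (340 higher and 335 lower). In a fit with distance class as a block, 76 were higher and 134 lower, and without the depth covariate 66 and 97. None of 7 lists had a camera adjusted p below 0.876.

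**Figure D3:**
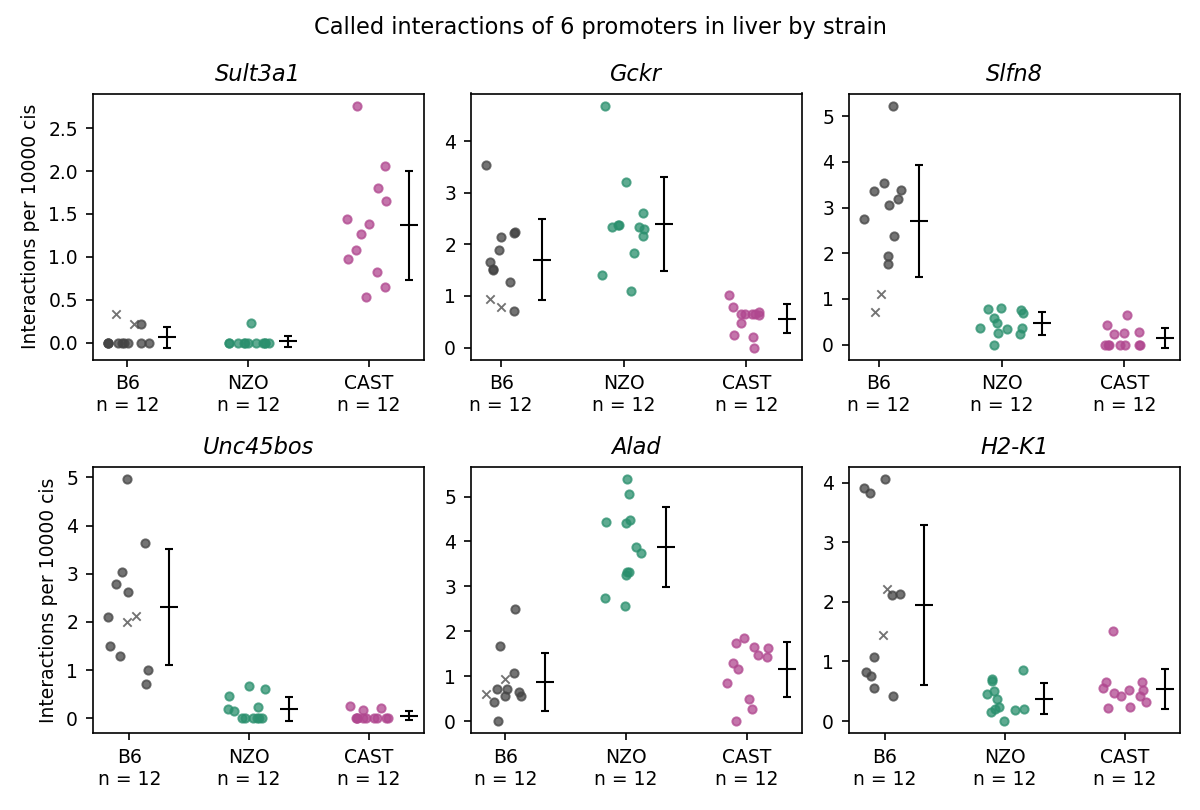
Called interactions per 10000 called cis interactions of each liver library for the promoters of Sult3a1, Gckr, Slfn8, Unc45bos, Alad and H2-K1 in B6, NZO and CAST (12 libraries each). Circles are long-distance and crosses short-distance libraries, and bars are the mean ± SD. Sult3a1 is highest in CAST and Alad in NZO, and Gckr is lowest in CAST.

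In NZO adipose, Alad had 20.4 ± 6.23 called interactions (SD, n = 12) against 4.92 ± 4.85 in B6 (n = 12), a rise of 2.30 ± 0.23 (edgeR adjusted p = 1.42e-12; 12 of 12 libraries). Rsph3b (2.39 ± 0.33), Olfr112 (2.01 ± 0.32), the myeloid receptor gene Cd300e (1.95 ± 0.42) and Cox6a2 (1.91 ± 0.31) rose. Unc45bos (-3.11 ± 0.41), H2-K1 (-2.79 ± 0.38; 12 of 12 libraries), Zfp82 (-2.18 ± 0.48), Clec2d (-1.89 ± 0.45) and Slc9a3r2 (-1.74 ± 0.35) fell. Over all promoters 188 were higher and 180 lower of 11776. These 368 fell to between 37 and 80 without 1 replicate of every group, and with summed reads 100 were higher and 637 lower. DESeq2 called 129, without Cd300e (1.58, adjusted p = 0.0734). With the class as a block, 100 were higher and 148 lower, without Zfp82 (-1.45, adjusted p = 0.143), and without the depth covariate 96 and 251. The 7 lists had camera adjusted p-values of 0.919 or above.

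In CAST adipose, Sult3a1 had 12.9 ± 9.80 called interactions (SD, n = 11) against 1.00 ± 1.95 in B6 (n = 12), a rise of 3.36 ± 0.36 (edgeR adjusted p = 1.82e-11; 11 of 11 libraries). Its neighbour Sult3a2 (4.17 ± 0.68) rose in 7 of 11 libraries and was not called by DESeq2 (3.92, adjusted p = 0.0765). Others that rose were Btbd9 (2.97 ± 0.36), Lemd2 (2.87 ± 0.40) and Glo1, the gene of a detoxifying glyoxalase (2.63 ± 0.46), which share a part of chromosome 17. Zfp273 (-2.73 ± 0.35), Ms4a6b (-2.67 ± 0.37), Slfn8 (-2.64 ± 0.33), Ifi47 (-2.40 ± 0.38) and Zfp729a (-2.37 ± 0.41) fell. Over all promoters 291 were higher and 976 lower of 11776, and without the depth covariate 466 and 710. With summed reads the excess of lower ones was absent (420 higher and 406 lower), and without 1 replicate of every group 295 to 544 were called in all. In the fit blocked by distance class, 37 were higher and 107 lower, and Ifi47 (-1.08, adjusted p = 0.338) and Zfp729a (-1.52, adjusted p = 0.0819) were not called. Within the long-distance libraries, of which 3 are CAST, 11 were called and none of the named promoters was. The changes there were 6.20 for Sult3a1, 4.21 for Btbd9, 4.97 for Lemd2, -5.19 for Zfp273, -4.87 for Ms4a6b, -3.69 for Slfn8 and -2.80 for Zfp729a, larger than over all libraries, and -1.21 for Ifi47, which was smaller. The 7 lists had camera adjusted p-values of 0.294 or above.

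In NZO islet, with 6 libraries, Itln1, the gene of a sugar-binding intelectin, had 5.50 ± 2.59 called interactions against 0.455 ± 0.820 in B6 (n = 11), a rise of 4.05 ± 0.58 (edgeR adjusted p = 1.79e-08) in 6 of 6 libraries. Cd244a, on a bait nearby, rose by 2.71 ± 0.41 and Alad by 2.18 ± 0.40, with Klhdc8b (1.36 ± 0.34) and Tlk2 (1.36 ± 0.32). Cenpv (-2.69 ± 0.67), Tmem267 (-2.47 ± 0.56), Elobl (-2.41 ± 0.52) and Hic1 (-1.92 ± 0.50) were among those that fell. Of 12 islet endocrine genes 0 rose and 0 fell by edgeR, or 0 and 2 over the list alone, with a camera adjusted p of 0.00769. That call was lost with an estimated correlation (adjusted p = 0.403) and with distance class as a block (adjusted p = 1). Over all promoters 10 were higher and 21 lower of 9033, and by DESeq2 9 and 5. The balance turned with all libraries (187 higher and 58 lower) and with summed reads (123 and 27). With the class as a block 4 and 3 were called, and Klhdc8b (0.87), Tlk2 (0.76), Cenpv (-2.69), Tmem267 (-2.01) and Hic1 (-1.10) were not, of which Cenpv kept the size of its change. Without replicate 3 of every group 249 were called and without replicate 1 the number was 4.

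In CAST islet, Itln1 rose by 3.15 ± 0.52 (edgeR adjusted p = 1.30e-06; 9 of 10 libraries), Glo1 by 2.80 ± 0.41, Sult3a1 by 2.44 ± 0.38, Lemd2 by 2.16 ± 0.47 and Slc37a1 by 2.11 ± 0.38. Zfp273 (-2.12 ± 0.41), the superoxide dismutase gene Sod2 (-2.04 ± 0.42), Tpst1 (-2.0 ± 0.35), Tmem267 (-1.74 ± 0.36) and Crcp (-1.73 ± 0.35) fell. Over all promoters 35 were higher and 81 lower of 9033, and by DESeq2 19 and 17. Without 1 replicate of every group 10 to 97 were called, and with summed reads 250. With distance class blocked, 17 and 32 were called, and Zfp273, Sod2, Tpst1 and Crcp were not (-1.46, -1.62, -1.40 and -1.14, with adjusted p = 0.148, 0.0525, 0.053 and 0.191). The lowest of the 7 list p-values was 0.206 (adjusted).

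Some strain effects were shared by tissues. A strain variant against the reference could be shared by tissues too, which was not tested for these calls. In NZO 5 promoters were called in all 3 tissues (Itln1 and Alad higher, Gm10037, Tmem267 and Hgsnat lower), of 518 called in any. In CAST 33 were called in all 3, 10 higher and 23 lower, of 2216. Hgsnat and Gm10037 were chosen after their values were seen. Of the promoters called in NZO liver, 88.6% had the same direction in NZO adipose (155 of 175), and 81.4% with distance class as a block. The same share was 64.2% for NZO liver in islet (95 of 148) and 46.4% for NZO adipose in islet (128 of 276), which with the block became 64.1% (109 of 170) and 68.7% (123 of 179). For CAST adipose in islet it was 87.1% (835 of 959), and 95.8% with the block (91 of 95). For CAST liver and adipose the share was 59.3% (647 of 1092), and 82.5% with the block (888 of 1076). Over all promoters tested in both liver and adipose, 63.0% had the same direction for NZO and 53.6% for CAST. Over all tested in both adipose and islet, the shares were 43.9% for NZO and 66.4% for CAST, and 54.2% and 59.5% with the block. For NZO in liver and islet the share over all tested was 47.5%, and 51.8% with the block.

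**Figure D4:**
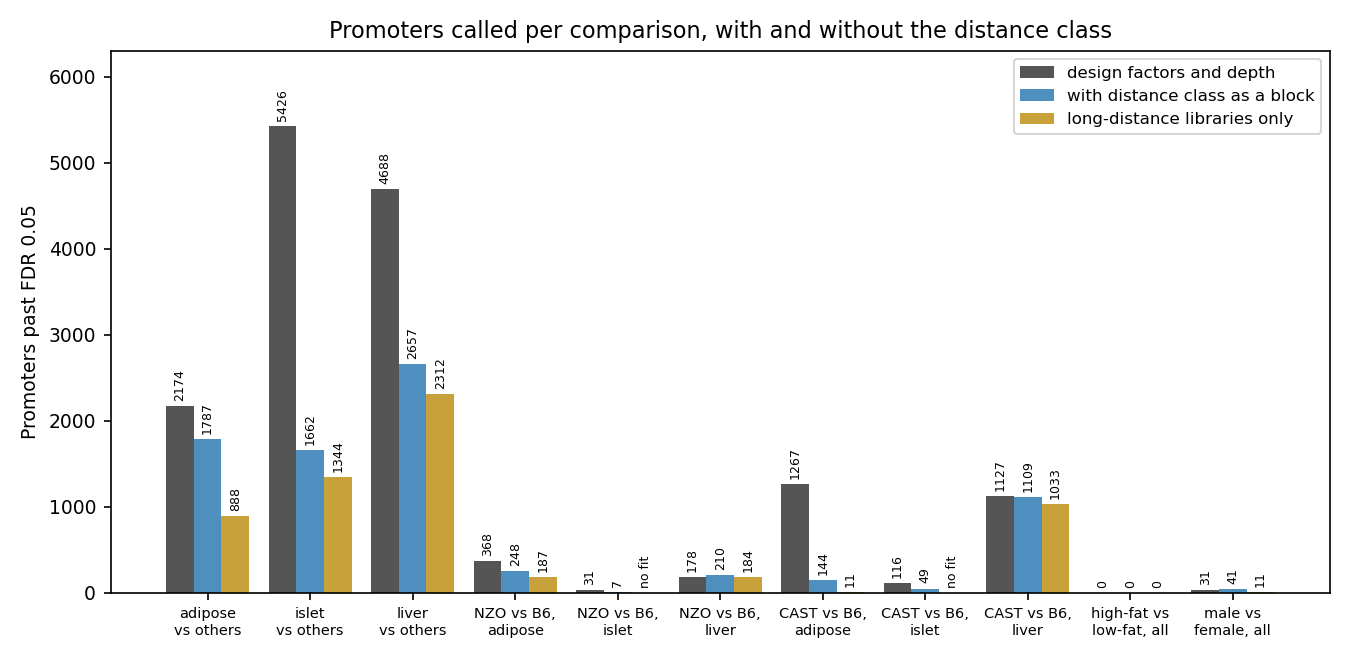
Number of promoters past an adjusted p of 0.05 in each comparison under the primary fit, with distance class as a block, and in long-distance libraries alone (not fitted for strain, diet and sex within islet). The islet count falls from 5426 to 1662 and 1344, and the CAST adipose count from 1267 to 144 and 11.

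The sexes differed at X and Y promoters. Over all tissues, 29 promoters were lower in males and all lie on the X chromosome, where 114 of 118 tested promoters had a negative log2 change and the median was -0.61. The 2 higher ones, Eif2s3y and Kdm5d, lie on the Y. These 31 calls leave no call by edgeR among 10843 autosomal promoters, and over all chromosomes 386 promoters had an unadjusted p under 0.05 and DESeq2 called 28. Without 1 replicate of every group 14 to 16 were called, and with summed reads 333 (80 higher and 253 lower). Kdm6a, a histone demethylase gene that escapes X inactivation, had 0.62 ± 1.10 called interactions in males (SD, n = 50) and 2.12 ± 1.61 in females (n = 48), a change of -1.60 ± 0.27 (edgeR adjusted p = 4.14e-05; 44 of 50 male libraries). Other promoters lower in males were Tfe3 (-0.90 ± 0.15), Timm17b (-0.85 ± 0.15), Fam50a (-0.67 ± 0.13) and Atp6ap1 (-0.57 ± 0.14), which lie on the X. Of 3 tested genes that escape X inactivation 1 fell, or 2 over the list alone, and the list passed camera (adjusted p = 2.12e-09, and 3.36e-07 with an estimated correlation). These genes lie on the X, where nearly all tested promoters were lower in males, and they were not compared with other X promoters. The pass therefore does not set escape genes apart from the rest of the X. Of 9 liver genes of known sex bias 0 changed, also over the list alone (adjusted p = 0.704), and of 21 lipid genes 0 (adjusted p = 1). Within the long-distance libraries 11 promoters were called, without Fam50a (-0.59, adjusted p = 0.062) and Atp6ap1 (-0.35, adjusted p = 0.999).

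Within adipose the 4 promoters that were higher in males were the Y genes Eif2s3y (2.00 ± 1.91 calls), Uty (2.17 ± 2.33), Kdm5d (1.61 ± 1.91) and Ddx3y (1.33 ± 1.33), which had none in the 17 female libraries. They were named after their values were seen, and DESeq2 called 1, Eif2s3y. Within islet 5 X promoters were lower in males, in 14 of 14 libraries each, namely Atp6ap1 (-1.81 ± 0.38), Timm17b (-1.63 ± 0.31), Pqbp1 (-1.70 ± 0.37), Rpl39 (-2.34 ± 0.55) and the unit of Apex2 and Pfkfb1 (-2.40 ± 0.57). DESeq2 called 2 of them. Within liver L1cam was lower (-1.83 ± 0.37, adjusted p = 0.049), which DESeq2 (0 calls) and the class block (-1.81, adjusted p = 0.0598) did not call. Of the lists in single tissues, the escape genes passed in adipose (adjusted p = 4.21e-04) and liver (adjusted p = 2.62e-04), again without a comparison with other X promoters. None of the 16 lipid genes was called by edgeR in islet or in liver, also over the list alone, while camera gave a shift of the list up in male islet (adjusted p = 0.0282, and adjusted p = 0.0518 with an estimated correlation) and down in male liver (adjusted p = 0.0388, and 0.249 with the class as a block).

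The X chromosome held 0.930% ± 0.242 of called cis interactions in male (SD, n = 18) and 1.40% ± 0.427 in female adipose (n = 17; permutation adjusted p = 0.00026). The shares were 0.469% ± 0.347 (n = 14) and 1.52% ± 0.404 (n = 13) in islet (permutation adjusted p = 4e-05) and 0.878% ± 0.155 and 1.26% ± 0.249 in liver (n = 18 each; permutation adjusted p = 6e-05). Within long-distance libraries the male and female means were 0.922% and 1.14% in adipose (permutation adjusted p = 0.00063), 0.768% (n = 3) and 1.00% (n = 4) in islet (exact adjusted p = 0.044) and 0.878% and 1.18% in liver (permutation adjusted p = 4.5e-05). Within short-distance libraries they were 0.945% (n = 6) and 2.01% (n = 5) in adipose (exact adjusted p = 0.0097), and 0.387% (n = 11) and 1.75% (n = 9) in islet (exact adjusted p = 4.5e-05).

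**Figure D5:**
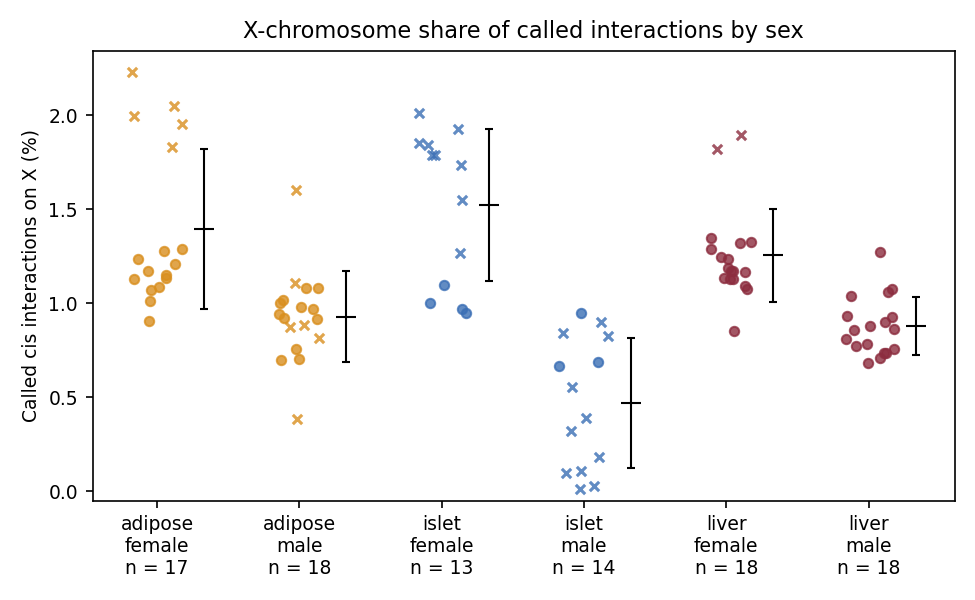
X-chromosome share of called cis interactions in percent for each library by tissue and sex. Circles are long-distance and crosses short-distance libraries, and bars are the mean ± SD. Male means are 0.930, 0.469 and 0.878% and female means 1.40, 1.52 and 1.26% in adipose, islet and liver.

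The diet comparison asks whether high-fat feeding moved promoter contacts. Over all tissues edgeR called 0 promoters of 10963 and DESeq2 0, with 519 and 465 at an unadjusted p under 0.05. With summed reads in place of counts of calls edgeR called 114 (32 higher and 82 lower), and within liver 166 (92 and 74), where 2 of 25 splits of the liver samples called as many. None of the lists for lipid metabolism (21 tested, camera adjusted p = 0.634), inflammation (17, 0.574), adipocytes (24, 0.637), islet endocrine cells (11, 0.574), hepatocytes (13, 0.649), type 2 diabetes signals (26, 0.634) or macrophages (9, 0.574) had a member that rose or fell by edgeR. Adjusted over the list alone 1 islet endocrine gene fell and no other. Within liver edgeR and DESeq2 called 0, with 413 and 241 at an unadjusted p under 0.05. Within adipose 1 promoter was called, Gm10037, at 10.2 ± 13.8 (n = 18) against 3.65 ± 3.12 calls (n = 17), but 8 of 18 high-fat libraries lay above the low-fat median, and with distance class as a block its adjusted p was 0.884. Within islet the histone unit of H2ac4 and H2bc3 was lower (-2.14 ± 0.43, adjusted p = 0.00648; 0.986 with the block). Both were named after their values were seen. DESeq2 called 0 in adipose and 0 in islet. No diet list in a single tissue had an adjusted p below 0.263. For single interactions limma called 0 of 112597, with 5403 at an unadjusted p under 0.05, and Fisher's exact test 0, with 2105. In simulated data 85.1% of promoters changed by 1 log2 unit were called over all tissues, 51.1% within liver, 36.3% within adipose and 9.8% within islet. Few calls within islet therefore say little about changes of this size. A test of whether the diet effect differs between tissues called 0 of 11562 by edgeR, with 827 at an unadjusted p under 0.05. For sex it called 0, with 796.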

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

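The tests of distance class, of calling depth and of between-chromosome pairs were chosen only after the results were seen, as were the splits for tissue and for diet and sex over all tissues. The splits within a tissue, for summed reads and for single interactions were planned.

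Of 10963 promoters, 5426 differed in islet from adipose and liver. In libraries with at least 10000 called cis interactions 4753 of these promoters were called, which argues against the libraries below that number as their source. This setting kept 92 of 98 libraries and did not match depth between tissues, so it cannot decide on depth beyond that. Distance class as the whole cause is argued against for 967 of the 5426, which were called within the long-distance libraries, of 1344 called there. The splits, which called 8 at most, were of all samples, and none was run within this class. The 7 islet libraries there held fewer calls (mean 17464, against 45190 in adipose and 39899 in liver). Their between-chromosome share was higher (42.9%, against 12.5% and 8.24%), so these calls do not separate tissue from library quality. Distance class as part of the cause may hold: with the class as a block a median of 38.1% of the log2 change was left. For the 4215 promoters whose call ended, the median size of the change went from 0.82 to 0.26, and its SE from 0.235 to 0.248. A smaller change is partly built in here, since these promoters were picked by the loss of their call. Of them, 78.4% kept their direction. The class goes with islet, so the block can take out tissue differences too. A tissue difference therefore stays open for these 4215 promoters and for the 1211 still called.

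The effect of strain differed between tissues at 2496 of 11562 promoters, by an edgeR test of the tissue by strain terms. With distance class as a block, 51 were called. Of the promoters called in CAST liver, 59.3% had the same direction in CAST adipose, and 82.5% with the block. The distance class, which holds 8 of 11 CAST adipose libraries and 0 of 12 CAST liver libraries on the short side, is a candidate explanation for most of the difference. All NZO adipose, NZO liver and CAST liver libraries are long-distance and all NZO islet libraries short-distance. The block can therefore take out strain differences too, and the drop to 51 does not show that class caused the others. A biological difference between tissues stays open for the 51 promoters called with the block and for the others.

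Between-chromosome calls were left out of the primary comparisons. Of 963 pairs called in at least 8 libraries, 281 were private to CAST, 164 to NZO and 5 to B6, that is called in at least 30% of the libraries of that strain and in at most 1 of each other strain. Of the 5 in B6, 4 join X 169971325 to 169981835 with Y 90799954 to 90815231. No cause was tested for these 4 pairs, and they are not shown to be contacts in the nucleus. With strain labels permuted 1000 times within tissue the highest counts were 1, 4 and 1, and 1 of 1001 label sets, the real one, reached the count for CAST and 1 of 1001 for NZO (p = 0.001, the smallest these permutations can give).

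Contacts of a single tissue are argued against: of pairs private within liver or within adipose alone, at least 78.0% in CAST and 91.8% in NZO were called in that strain in the other tissue, against at most 9.78% and 10.3% in another strain. Distance class is argued against for CAST, where 89.3% were called in both classes. Of the NZO pairs, 9.76% were called in both classes and 16 of 164 in all 3 tissues, against 214 of 281 CAST pairs in all 3. NZO adipose and liver libraries are all long-distance and islet libraries all short-distance, so this share cannot tell class from islet. Within liver 12 of 12 NZO, 12 of 12 CAST and 10 of 12 B6 libraries are long-distance. There 167 pairs were private to NZO, of which 95.8% were called in NZO adipose and 4.19% in B6 adipose. This argues against class as the cause for these 167 pairs. A strain variant against the reference, such as sequence placed elsewhere in that strain, may give such pairs, with 1 narrow end. Of the loci with at least 3 pairs, 86.7% in CAST and 89.5% in NZO had an end of at most 12 kb, against 78.1% of loci private to no strain, so a variant and a contact in the nucleus cannot be told apart by this.

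A Y-chromosome signal appeared in 1 female library, high-fat CAST liver replicate 1, with 6 interactions where the other female libraries had 0. All 18 male liver libraries held Y interactions, at most 12 each, so a count of 6 does not set this library apart from males. Its X share was 1.08% and it held 48395 called cis interactions. This share lies within the range of male liver libraries (0.685 to 1.27%) and of female ones (0.851 to 1.90%), so it cannot decide the sex. Whether the sex label is right was not tested, and the library counts as female in the sex comparisons. No biological explanation was tested for the Y signal.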

How the results depend on the processing

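The distance class as a block, the fits within the long-distance or short-distance libraries, and the fits without the 5 libraries rich in between-chromosome calls were chosen after seeing the data; the other alternatives were planned. The cause of a change was not tested unless it is stated. No paired analysis was run, because replicate numbers follow the order of deposition. Whether libraries of different tissues came from the same animal was not examined, and all tests treat the libraries as independent.

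With DESeq2 the counts of promoters went from 368 to 129 for NZO adipose, 31 to 14 for NZO islet, 116 to 36 for CAST islet and 178 to 93 for NZO liver. For diet they went from 1 to 0 in adipose and 1 to 0 in islet, and for sex from 4 to 1 in adipose, 5 to 2 in islet and 1 to 0 in liver. With the number series of the titles as a block they were 219 for NZO adipose, 20 for NZO islet, 76 for CAST islet, 0 for diet in adipose and in islet, 8 for sex in islet and 0 for sex in liver. Series A is all low-fat and B all high-fat, so with this block diet is compared only within series C and its diet counts say little. Without the depth covariate they were 14 for NZO islet, 62 for CAST islet, 0 for diet in adipose and in islet, and 0, 3 and 5 for sex in adipose, islet and liver. Without a filter they were 8657 for islet, 100 for sex over all tissues, 288 for CAST islet, 2 for diet in islet, 16 for sex in islet and 6 for sex in liver.

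With a score of at least 7, which leaves fewer calls by construction, they were 771 for adipose, 1804 for islet, 1571 for liver, 1 for sex over all tissues, 571 for CAST adipose, 13 for NZO islet, 53 for CAST islet, 88 for NZO liver, 444 for CAST liver, and 0, 1 and 0 for sex in adipose, islet and liver. Single interactions then numbered 2234 in adipose, 8575 in islet and 8670 in liver. Fisher's exact test called 11519 of them in liver.

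Summed reads moved the median log2 change of all promoters to 0.39 in islet, -0.31 in liver, 0.29 in CAST adipose, -0.15 in NZO adipose and 0.17 in CAST islet. They gave 114 for diet and 333 for sex over all tissues, 737 for NZO and 826 for CAST adipose, 150 for NZO and 250 for CAST islet, 675 for NZO and 1704 for CAST liver, 5 and 166 for diet in islet and liver, and 40, 61 and 111 for sex in adipose, islet and liver.

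With all libraries NZO islet had 245, and the promoter-promoter share of adipose minus islet went from 7.54 to 4.03 points (adjusted p = 0.11). In libraries with at least 10000 calls the counts were 20 for sex over all tissues, 0 for diet in adipose, 16 for NZO islet and 2 for sex in islet. There the log10 number of calls differed by 0.12 for adipose minus islet (adjusted p = 0.18), 0.14 for adipose minus liver (adjusted p = 0.018) and 0.0248 for islet minus liver (adjusted p = 0.74), a reversal. This setting selects libraries by the number that is compared, so these differences in calls say little. At depths of 20000 to 60000 the median distance of adipose minus liver went from -14.0 to -5.76 kb (adjusted p = 0.15). With between-chromosome calls included the counts were 0 for diet in adipose, 68 for NZO islet, 180 for CAST islet and 5 for sex in liver. Without the libraries rich in them they were 0 for diet in adipose, 47 for NZO islet, 3 for sex in islet and 4 for sex in liver, and the log10 number of calls of adipose minus liver was 0.13 (adjusted p = 0.024).

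With distance class as a block the counts were 1662 for islet, 2657 for liver, 144 for CAST adipose, 7 for NZO islet, 49 for CAST islet, 7 for sex in adipose, and 0 for diet in adipose and in islet. Single interactions numbered 2312 in adipose, 1071 in islet and 4850 in liver, and the tissue by strain test 51. The log2 change of Ciart in islet reversed from 1.76 to -0.0465 (adjusted p = 0.925). In islet the lists passed for endocrine genes (7.82e-05), hepatocytes (0.0221), type 2 diabetes signals (0.0394) and macrophages (0.0118), and no longer for housekeeping genes (0.0972). Endocrine genes in NZO islet (1) and lipid genes by sex in liver (0.249) no longer passed. With an estimated correlation, housekeeping genes in islet (0.111), endocrine genes in NZO islet (0.403) and lipid genes by sex in islet (0.0518) did not pass.

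Within the long-distance libraries the counts were 888 for adipose, 1344 for islet, 2312 for liver, 11 for sex over all tissues, 187 for NZO adipose, 11 for CAST adipose and 0 for diet in adipose. Single interactions numbered 233, 286 and 2061, and the Nr1i3 interaction in liver reversed from 34.0 to -9.43 points (adjusted p = 0.705). The promoter-promoter share of adipose minus islet reversed to -0.279 points (exact adjusted p = 0.85), and that of islet minus liver was -1.48 (exact adjusted p = 0.21). The test of tissue by diet called 1 promoter, H1f4, and that of tissue by sex 1, Creb3. Within the short-distance libraries the share of adipose minus islet reversed to -1.24 points (permutation adjusted p = 0.3), and the overlap difference reversed from 0.0371 to -0.00422 (permutation p = 0.9). Within islet the long-distance libraries hold no NZO and 1 CAST library among 7, so the strain contrasts could not be fitted there, and a smaller model for diet and sex was not run.

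Without replicate 1, 2 or 3 of every group the counts ranged from 997 to 1319 for adipose, 3745 to 4670 for islet, 3156 to 3824 for liver, 0 to 0 for diet and 14 to 16 for sex over all tissues. They were 37 to 80 for NZO and 295 to 544 for CAST adipose, 4 to 249 for NZO and 10 to 97 for CAST islet, and 78 to 90 for NZO and 569 to 603 for CAST liver. For diet they were 0 to 3, 0 to 0 and 0 to 0, and for sex 0 to 3, 0 to 4 and 0 to 0, in adipose, islet and liver. The 249 came without replicate 3. Single interactions ranged from 1073 to 2069, 11499 to 13357 and 10838 to 13027. The log10 number of calls ranged from 0.70 to 0.78 for adipose minus islet, 0.02 to 0.13 for adipose minus liver and -0.76 to -0.61 for islet minus liver. The promoter-promoter share ranged from 4.78 to 10.3, -7.27 to -5.74 and -17.4 to -12.0 points in that order, and the median distance from 9.44 to 21, -16.2 to -11.7 and -34.9 to -25.7 kb. Adipose minus islet did not pass without replicate 3 for the share (adjusted p = 0.15) or the distance (adjusted p = 0.25), nor did adipose minus liver without replicate 2 for the distance (adjusted p = 0.096). The X share of males minus females ranged from -0.503 to -0.434 in adipose, -1.24 to -0.772 in islet and -0.410 to -0.358 in liver, and the overlap difference from 0.0322 to 0.0402.

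With DESeq2, the number series or the distance class as a block, or the long-distance libraries alone, 363 of 421 values for named promoters stayed on their side of the threshold, 57 no longer passed and 1 reversed. For named interactions, with the class block or the long-distance libraries alone, these were 23, 10 and 1 of 34. Named genes were not followed through the other settings.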

Other observations

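The splits for tissue and for diet and sex over all tissues were chosen after the results were seen, and those within a tissue, for summed reads and for single interactions were planned. Each comparison was repeated on 50 splits of its samples, the real one included, or 25 for summed reads.

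Chance can be excluded for tissue, where 1 of 50 splits reached the real counts of 2174, 5426 and 4688 promoters for adipose, islet and liver and the highest others were 1, 8 and 0. It can be excluded for single interactions (4611, 23309 and 22004, with the highest others 2, 2 and 1). In liver, chance can be excluded for NZO (178; highest other 1) and CAST (1127; highest other 2). It can also be excluded for sex over all tissues (31; highest other 7).

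In adipose no other split reached the counts for NZO (368, highest other 291) and CAST (1267, highest other 231), nor in islet that for CAST (116, highest other 62). Splits that call this many promoters point to a structure of the samples. The NZO adipose count alone therefore does not exclude chance firmly, and it was 37 to 80 without 1 replicate of every group. With distance class as a block the real counts were 248, 144 and 49. For sex, 2 of 50 splits were as high in adipose (4, highest other 42) and in liver (1, highest other 1). That is under 5%, but 1 more such split would leave chance open, so these counts alone do not exclude it firmly. In adipose the 4 calls are the 4 tested Y promoters, with 0 autosomal calls. There 16 of 18 male libraries held Y interactions (182 in all), and 0 of 17 female libraries did. These values argue against chance for the Y signal in adipose. The liver call was lost with DESeq2 and without any 1 replicate of every group (0 called). The split that called 42 in adipose points to a structure of the samples. With the class as a block the count in adipose was 7.

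Chance cannot be excluded for NZO islet (31, highest other 78, with 3 of 50 splits as high) or sex in islet (5, highest other 19, with 3 of 50). Some other splits called more than the real counts there and point to a structure of the samples. With the class as a block the real counts were 7 and 5. The number of calls alone leaves sex in islet open, but all 5 lie on the X, where 71 of 72 tested promoters were lower in males, and the X share differed (permutation adjusted p = 4e-05), so chance is excluded for a lower X signal in males. Chance cannot be excluded for diet in adipose (1; highest other 7, with 4 of 50) and islet (1; highest other 8, with 9 of 50). For diet over all tissues and in liver the real counts by edgeR were 0 (519 and 413 at an unadjusted p under 0.05, and 0 by DESeq2), so 50 of 50 splits were as high, with the highest others 4 and 5. For single interactions by diet the count by limma was 0 (5403 at an unadjusted p under 0.05, and 0 by Fisher's exact test), with the highest other 1. With summed reads 166 promoters were called for diet in liver, and 2 of 25 splits were as high, the highest other calling 245, so chance cannot be excluded there either and these splits point to a structure of the samples.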
